A study of Mus musculus with 2 samples.

How the data were processed

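Total RNA from uterine epithelial cells of mice at day 4 of pregnancy was hybridised to the Affymetrix Mouse Genome 430A 2.0 array, a short oligonucleotide array. Per the labels' protocols, epithelium was separated from opened uterine segments by trypsin digestion, first cold and then warm, and by squeezing the tissue, and 100 ng of total RNA was labelled per array. The series' design text states n = 3 for each sample and that RNA was pooled, so each array reads 1 pool. There were 2 samples, 1 control and 1 Stat3 knockout. The group of each sample was taken from its genotype label, which reads control or Stat3 knockout. Both samples carry the same title, which names Stat3 flox control mice, while genotype and description separate them. The labels' extraction text names human endometrial stromal cells, against the mouse epithelium named everywhere else, and the tissue collection text mentions days 4 and 5; the organism, cell type and day given in the sample characteristics were used.

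The authors deposited 1 intensity value per probe set and array. The submitters' processing notes name MAS5 and Affymetrix Expression Console 1.1. The deposited intensity values were on a linear scale, between 0.0230 and 8267, and their mean after leaving out 2% of probe sets at each end was 150.1 on both arrays, so they had been scaled to a common level before deposit, as the values show. Detection calls, scanner images and probe-level values were not used here, and hybridisation batch and date are not given in the sources used here. No alternative background correction at probe level could be tried for that reason.

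The table held 22690 probe sets, of which 64 were Affymetrix controls. Of the other 22626, 20380 were paired with 1 gene, 691 with several and 1555 with none in the platform annotation, which may be old; the last 2 kinds were not named. Gene symbols were updated by gene ID through a RefSeq gene table (GRCm38.p6), which held the gene ID of 20351 (99.9%) of the probe sets with 1 gene. No genome was used, so no positions are given. Each gene was represented by the probe set with the highest mean log2 signal over both arrays, which gave 12393 genes. Probe sets whose name ends in _a_at, _s_at or _x_at can read several transcripts or genes; an alternative leaves these probe sets out. Of 348 genes past the 2-fold limit with a second measured probe set, 9 had the other direction in that probe set. In 242 it was past the limit in the same direction. For Acvr1, Cflar, H2-D1 and Jun, named as past the limit, another measured probe set had the same direction within 2-fold.

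Signals under a floor, the 40th percentile of all signals that are not controls (14.0), were set to the floor. The 4089 genes under it on both arrays have no ratio. For the 791 genes under it on 1 array, the fold is a bound against the floor and is given as "at least". The log2 ratio of knockout over control was computed per gene, with no pseudocount, and genes were counted at 2-fold in either direction. With 1 array per group no test across animals exists, and no p-value, SD or SE of a group was computed. Arrays give no counts, so no counting interval applies. The disagreement between probe sets of 1 gene is the only error measured on the gene ratios, and it covers neither animals nor arrays. Spike-in probe sets compare the 2 arrays for added transcripts only, with log2 ratios of -0.33 to 1.06 for poly-A and -0.26 to 0.36 for hybridisation spike-ins.

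Before the data were examined, 45 gene lists with 1021 gene names were fixed, 908 of which a probe set of 1 gene named on the array. They cover signalling, cell cycle, hormone response, junctions, immune response, transport, matrix and metabolism, and 9 of them are cell type markers. For each list with at least 5 measured members, the median log2 ratio, with bounds entered at their bound, was placed among the medians of 10000 random lists of the same size, matched on mean log2 signal in 20 bins, and described as outside the random range when among the lowest or highest 2.5% of positions. This describes these arrays and is not a test across animals. The rule for naming genes was also fixed before: Stat3 with all probe sets; the 15 largest increases and 15 largest decreases over the floor on both arrays, at least 2-fold, with all other measured probe sets in the same direction; the 5 brightest genes per direction that were under the floor on the other array; and from each list up to 6 members past 2-fold with the largest ratio and up to 3 others with the highest signal. Genes without an ordinary symbol were not named.

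Alternatives changed 1 choice at a time: the scaling between arrays (centring on the median log2 signal, quantile normalization, or loess on mean signal with a span of 0.3), the floor (20th or 60th percentile, none, or the floor value added to both signals), the mean of all probe sets of a gene, probe sets shared between transcripts left out, random lists without matching, list members of other lists left out, and limits of 1.5-fold and 3-fold. A floor at a signal of 100 was added after the data were seen. The calculations were tested on simulated data. Arrays were drawn from the real mean signals with the disagreement between probe sets as noise, and 200 genes with a mean signal over 100 were changed. The 2-fold limit was reached by 42.6% of 68 genes changed 2-fold, as the limit equals the true change, by 100% of 78 genes changed 4-fold and 100% of 54 changed 8-fold, and by 0.0409% of 7340 unchanged genes. Of 200 unchanged lists of 20 genes, 4.5% lay outside the random range, and 100% of 100 lists raised by 0.5 lay above it. The unchanged lists were themselves random draws, so their share follows from the rule. The real log2 ratios had a larger spread (robust SD 0.62) than the simulated noise (SD 0.28), and genes were simulated as independent. These shares therefore check the calculations and do not carry over to the real arrays. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.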

Results

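Transcript levels were measured in uterine epithelium taken from pregnant mice in the morning of day 4, in a control group and in a Stat3 knockout group. Each group was represented by 1 array, hybridised with total RNA pooled from 3 animals or preparations (n = 3 per sample in the design text, without a further definition). The comparison asks which epithelial transcripts differ when Stat3, the transcription factor that carries leukaemia inhibitory factor and interleukin 6 family signals to the nucleus, has been deleted, around the time when the epithelium becomes ready for embryo attachment. Values are MAS5 signals, the brightness of an Affymetrix probe set after background correction, on a linear scale. The number of arrays limits the precision: with 1 array per group no difference between the groups has a replicate check, so no p-value was computed and differences are described by size.

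Both arrays had been scaled to the same level, with a mean signal of 150.1 after removal of 2% of probe sets at each end. The median signals were 32.1 in the control and 30.7 in the knockout. The ratio of 3' to 5' signal, which rises with RNA degradation, was 0.736 in the control and 0.699 in the knockout for Gapdh, and 1.504 and 1.561 for Actb. For Pcx it was 19.9 and 21.97. The array reads each spike-in control with 2 designs of probe set, marked r2 in their names or not. The median log2 ratio (knockout over control) of the hybridisation spike-in probe sets was 0.18 in the 9 of the r2 design and -0.018 in the 9 others, and that of the poly-A spike-in probe sets was 0.20 in the 12 of the r2 design and 0.28 in the 12 others. Single hybridisation probe sets ranged from -0.26 to 0.36. Single poly-A probe sets ranged from -0.33 to 1.06, the highest of them past a 2-fold difference. The 5' probe sets had 0.80 and 0.99 for the spike-in dap and 1.06 and 0.69 for thr. Their 3' probe sets had 0.20 and 0.40, and 0.20 and 0.16. For phe the 5' ones had 0.06 and 0.39 and the 3' ones 0.02 and 0.20. For lys the 5' ones were lower (-0.06 and -0.33) than the 3' ones (0.29 and 0.11). The cause was not tested.

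The targeted gene was lower in the knockout array. Stat3 (gene ID 20848) had a signal of 582 in the control and 186 in the knockout for probe set 1460700_at, a log2 ratio of -1.64, or 3.12-fold lower, which left 32.0% of the control signal. For probe set 1426587_a_at the signals were 430.0 and 160.0, which was 2.69-fold lower (log2 ratio -1.43) and left 37.2%. The remaining probe set of the gene, 1424272_at, was under the floor of 14.0 on both arrays, with signals of 6.66 and 3.35. The array labelled as knockout therefore had the lower Stat3 signal. Whether these probe sets lie inside the deleted part of the gene was not determined here, and a probe set outside it would not check the deletion itself.

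Of 12393 genes represented by a probe set of 1 gene, 8304 were over the floor on at least 1 array and received a ratio. In the knockout, 612 genes (7.37%) were at least 2-fold higher and 824 (9.92%) at least 2-fold lower, while 6868 lay in between. The large differences were mostly decreases: 256 genes were at least 4-fold lower and 59 at least 4-fold higher, and 87 against 8 differed by at least 8-fold. Among the 7513 genes over the floor on both arrays, the median log2 ratio was 0.06, with quartiles of -0.38 and 0.46 and a robust SD of 0.62, and the log2 signals of the arrays had a Pearson r of 0.896 across genes, which are not independent replicates. Where a gene had a second measured probe set, log2 ratios of the same gene differed between probe sets with an SD of 0.28 per probe set (2853 genes). Of 348 genes past the 2-fold limit with a second probe set, 339 (97.4%) had the same direction in it. In 242 of the 348 the second probe set was also past the limit in that direction. This spread covers the probe sets and neither animals nor arrays. The counts depend on the floor and the fold limit: with no floor they were 1927 higher and 1774 lower, and at 3-fold 143 and 401.

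**Figure D1:**
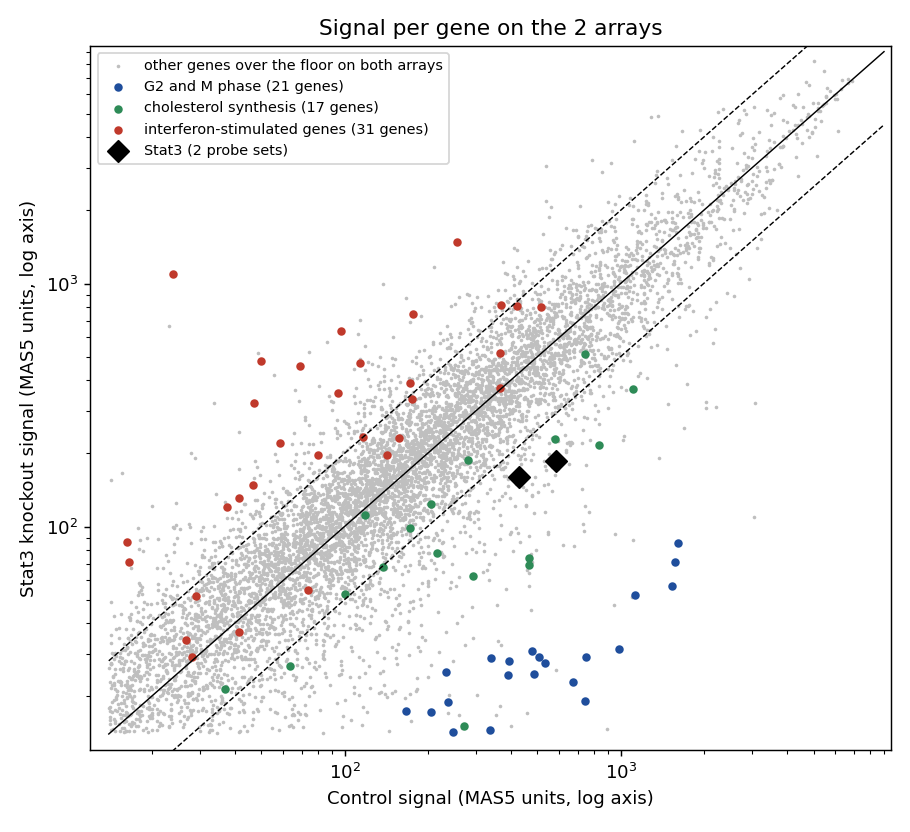
Signal of each gene on the control array (horizontal, MAS5 units, log axis) and on the Stat3 knockout array (vertical, MAS5 units, log axis), for the 7513 genes over the floor on both arrays. The solid line marks equal signals and the dashed lines a 2-fold difference; members of 3 gene lists are coloured and diamonds mark the 2 measured Stat3 probe sets, at 582 against 186 and 430.0 against 160.0, both below the lower dashed line.

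Of the 43 gene lists with a median, those of cell division had the lowest ones. All 29 measured genes of the G2 and M phase list were at least 2-fold lower in the knockout, with a median log2 ratio of -4.12, and 25 of 29 genes of the DNA replication and S phase list were at least 2-fold lower and 0 higher, with a median of -1.91. Random lists of the same size and signal gave medians of -0.26 to 0.33 for the first list and -0.26 to 0.35 for the second (leaving out 2.5% of them at each end). Mki67, which encodes the proliferation marker Ki-67, had a signal of 742 in the control and 19.1 in the knockout, or 38.9-fold lower. The mitotic kinase gene Cdk1 was 31.6-fold lower (990 and 31.3), Birc5, which encodes the chromosomal passenger protein survivin, 29.4-fold lower (674 and 22.9), Cdc20, an activator of the anaphase-promoting complex, 27.1-fold lower (1533 and 56.7) and Ccna2, which encodes cyclin A2, 25.6-fold lower (748 and 29.1). The kinetochore and chromosome genes Cenpf, Top2a and Mad2l1 were 23.2-fold, 22.1-fold and 21.6-fold lower. The checkpoint kinase gene Bub1 was at least 26.8-fold lower and the kinase gene Melk at least 21.98-fold lower, both under the floor in the knockout.

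In the replication list, Rrm2, the small subunit of ribonucleotide reductase, was 26.8-fold lower (459 and 17.1) and Uhrf1, which takes part in the maintenance of DNA methylation, 26.6-fold lower (401 and 15.1). The replicative helicase genes Mcm5 and Mcm3 were 11.1-fold and 8.12-fold lower, and Mcm7 and Mcm6 2.70-fold and 3.15-fold lower. Pcna, the sliding clamp of DNA polymerase, kept a signal of 783 in the knockout against 2109 in the control, or 2.69-fold lower. Pclaf, which encodes a PCNA-binding protein, and Shcbp1 were 21.4-fold and 21.2-fold lower.

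Outside the cell cycle, the most decreased genes over the floor on both arrays were Padi1, a peptidylarginine deiminase gene, at 60.9-fold lower (890.4 and 14.6), Lcn2, which encodes the iron-siderophore binding protein lipocalin 2, at 28.0-fold lower (3051 and 109), and Prss22, a serine protease gene, at 22.7-fold lower (584 and 25.7). Mfsd4a, Sulf2 and Serpina1c were bright in the control and under the floor in the knockout, at least 35.5-fold, 22.7-fold and 22.1-fold lower.

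Of 27 measured STAT3 target and feedback genes, 12 were at least 2-fold lower in the knockout and 3 at least 2-fold higher. Egr1 was among these 3, at 2.68-fold higher (462 and 1239). The list's median log2 ratio was -0.64, against -0.24 to 0.32 in matched random lists; 13 of the 27 genes also belong to another list, Birc5 among them to the G2 and M phase list. Besides Birc5 and Lcn2, the NF-kappa-B cofactor gene Bcl3 was at least 12.1-fold lower (signal of 169.9 in the control), Osmr, which encodes the oncostatin M receptor, 8.62-fold lower (182 and 21.1), Myc 6.55-fold lower (136 and 20.8), and Timp1, an inhibitor of matrix metalloproteinases, at least 5.02-fold lower. The 3 brightest members within the 2-fold limit were Hif1a, with signals of 3079 and 3757, the immediate early gene Fos, with 1967 and 3147, and Mcl1, with 827 and 870.3. Dimmer probe sets of Hif1a were past the limit, with signals of 403 and 1233 (log2 ratio 1.61) and of 57.4 and 170.3 (1.57). The JAK-STAT list of receptors, kinases and STATs had 2 genes higher and 3 lower among 22, and its median of 0.07 lay inside the random range. Il6 (4.49-fold, 17.95 and 80.6) and Stat2 (3.03-fold, 18.5 and 56.1) were higher, Lif, the ligand made by uterine glands before implantation, was at least 2.12-fold lower from a control signal of 29.8, and Jak2 had signals of 1285 and 1936.

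The dissociation and immediate early gene list, which holds genes that respond quickly to stimuli and to tissue dissociation, had 8 of 26 genes at least 2-fold higher and 2 lower, with a median log2 ratio of 0.48 (random range -0.22 to 0.31). Dusp1, a MAP kinase phosphatase gene, was 3.26-fold higher (375 and 1225), Egr1 2.68-fold (462 and 1239) and Jun 2.23-fold (780.0 and 1738). Among the heat shock genes of the same list, Hsph1 was 2.81-fold lower and Hspa8 had signals of 6141 and 4230.

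Interferon-stimulated genes had the highest median of the 43 lists. Of 31 measured genes, 19 were at least 2-fold higher in the knockout and 0 at least 2-fold lower, with a median log2 ratio of 1.30 against -0.26 to 0.32 in random lists. Iigp1, an interferon-inducible GTPase gene, had a signal of 23.8 in the control and 1099 in the knockout, or 46.2-fold higher, the largest increase among genes over the floor on both arrays. Oasl2 was 9.67-fold higher (49.8 and 481), the guanylate-binding protein gene Gbp2 6.87-fold (47.1 and 323), the GTPase gene Igtp 5.80-fold (257 and 1488), and Psmb9, a subunit of the immunoproteasome, 6.57-fold (97.3 and 639). Gbp8 and Cd274, which encodes the immune checkpoint ligand PD-L1, were under the floor in the control and at least 5.78-fold and 8.43-fold higher in the knockout. Markers of macrophages and dendritic cells also had a median above the random range, 0.67 against -0.42 to 0.47, with 1 of 12 genes, C1qa (33.2 and 67.4), at least 2-fold higher. Without the 5 members that other lists hold, that median was 0.47 and no longer outside its range.

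Antigen presentation genes showed the same direction, with 5 of 11 at least 2-fold higher, 0 at least 2-fold lower and a median of 0.80 (random range -0.40 to 0.48). The peptide transporter gene Tap1, counted among the interferon-stimulated genes, was 6.61-fold higher (69.2 and 457). The class I genes H2-K1 and H2-D1, whose probe sets can also read related class I genes, were 3.77-fold (1290 and 4858) and 2.10-fold higher (1541 and 3237), and B2m, the light chain of class I molecules, 2.25-fold higher (2261 and 5089). Of the class II genes, H2-Aa and H2-Eb1 had signals of 135 and 169.9, and of 69.6 and 112, beside the median of 0.67 of the macrophage and dendritic cell markers, cells that carry class II molecules. A dimmer H2-Aa probe set had signals of 42.9 and 83.5 (log2 ratio 0.96).

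The lists of genes that respond to the ovarian hormones differed in opposite directions. In the oestrogen list, 11 of 31 genes were at least 2-fold lower in the knockout and 2 at least 2-fold higher, with a median log2 ratio of -0.40 (random range -0.21 to 0.30). Besides Padi1, Lcn2 and Mad2l1, Sprr2f, a small proline-rich protein gene, was 9.55-fold lower (3075 and 322), Padi4 6.38-fold lower (254.5 and 39.9) and the water channel gene Aqp5 at least 8.44-fold lower. Krt19 and Cd14 had signals of 2884 and 3329, and of 1262 and 2101. In the progesterone list, 5 of 27 genes were at least 2-fold higher and 3 at least 2-fold lower, with a median of 0.38 (random range -0.22 to 0.31). Spink1, a trypsin inhibitor gene, was 10.9-fold higher (14.2 and 155), the sulfotransferase gene Sult1d1 4.08-fold (791 and 3228) and Per1 3.65-fold higher, while Ctsl, which encodes cathepsin L, was 2.74-fold lower (1479 and 540). The median of the progesterone list fell inside the random range under 5 of the alternative settings, among them with the members of other lists left out (0.21).

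Among the 27 measured implantation-related epithelial genes, 3 were at least 2-fold higher and 7 at least 2-fold lower, and the median of 0.12 lay inside the random range. Klf4, a Krüppel-like transcription factor gene, was 4.51-fold lower (1738 and 386), Muc1, a cell surface mucin gene, 4.22-fold lower (418 and 99.0), Igfbp3 3.83-fold lower and Msx2 2.90-fold lower, while the kinase gene Sgk1 was 3.40-fold higher (922 and 3140). Calb1 and Sox17, both bright, had signals of 5018 and 8267, and of 2802 and 5185. A dimmer probe set of each was past the limit, with signals of 198 and 1192 for Calb1 (log2 ratio 2.59), whose brighter one had the highest signal of the knockout array, and of 1369 and 2873 for Sox17 (log2 ratio 1.07). Of 9 measured EGF family ligands and receptors, Egfr was 2.97-fold higher (81.6 and 242.5), the ligand gene Nrg4 2.42-fold higher, and Lrig1, a negative regulator of the receptors, 5.83-fold lower (545.5 and 93.5). A dimmer Egfr probe set had signals of 40.8 and 61.2. The receptor gene Erbb3 had signals of 511 and 736, and the list's median of 0.24 lay inside the random range.

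Cell junction genes differed in both directions. Tight junction genes had a median of 0.48 (random range -0.30 to 0.35), with 4 of 20 at least 2-fold higher and 2 at least 2-fold lower. The claudin genes moved apart: Cldn1 was 7.17-fold higher (27.9 and 200.0), Cldn8 4.18-fold, Cldn15 3.18-fold and Cldn4 2.09-fold higher (371 and 776), Cldn10 was 4.03-fold lower (319 and 79.2), and Cldn7 had signals of 3349 and 3341. The Cldn1 value comes from a probe set that can read several transcripts. Another Cldn1 probe set, under the floor in the control, had signals of 2.05 and 19.7, a log2 ratio of at least 0.49. Of 14 adherens junction genes, the nectin genes Nectin3 and Nectin4 were 2.39-fold and 2.30-fold lower, and 12 lay within 2-fold, among them Cdh1, which encodes E-cadherin (2275 and 2708), and Ctnnb1, which encodes beta-catenin (3590 and 3811). Among 12 desmosome and hemidesmosome genes, Dsc2 was 3.81-fold lower (171 and 44.9) and Dst and Ppl were 3.37-fold and 2.30-fold higher. Other probe sets of Nectin4, of Nectin3 and of Dsc2 stayed within 2-fold, with signals of 47.0 and 43.6, of 159.6 and 93.2, and of 27.7 and 18.2. Of 21 apicobasal polarity genes, only Podxl passed the limit, at 2.71-fold higher, and Ezr and Cdc42 had signals of 1797 and 1903, and of 1790 and 1579. Among 17 keratin and epithelial identity genes, Krt7 was 3.46-fold lower (1592 and 460) and the transcription factor gene Ehf 2.35-fold higher, while Krt8 and Krt18 had signals of 4220 and 4289, and of 3180 and 4202. The medians of these last 4 lists lay inside their random ranges. Krt10, a keratin gene outside the list, was 7.18-fold higher (138 and 993).

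**Figure D2:**
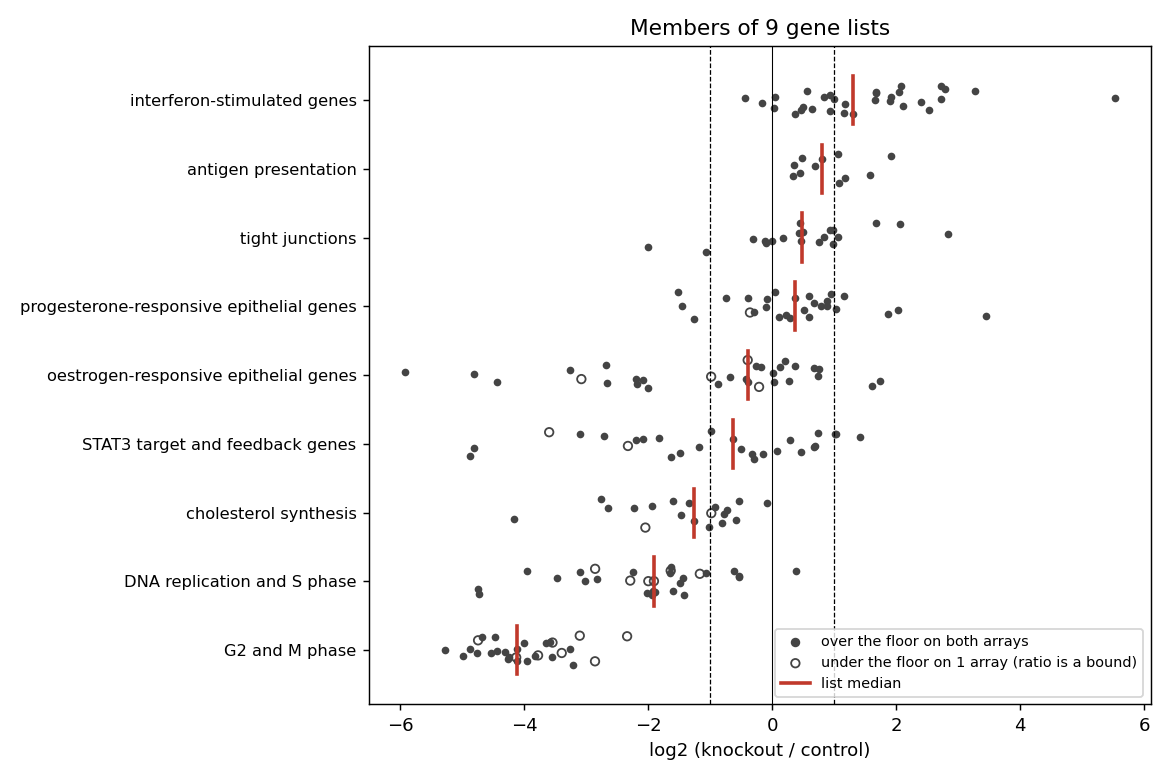
Log2 ratio of knockout over control (horizontal) for the measured members of 9 gene lists; each point is 1 gene, open points are bounds because the gene was under the floor on 1 array, the red line is the list median and dashed lines mark a 2-fold difference in either direction. All 29 G2 and M phase genes lie left of the lower dashed line, and 19 of 31 interferon-stimulated genes lie right of the upper one.

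Cholesterol synthesis genes were lower together. Of 19 measured genes, 11 were at least 2-fold lower in the knockout, 0 were at least 2-fold higher, and all 19 had a log2 ratio under 0, with a median of -1.26 (random range -0.34 to 0.39). Sqle, which encodes squalene epoxidase, was 17.97-fold lower (271.5 and 15.1), Msmo1 6.74-fold lower (467 and 69.2), Idi1 6.30-fold lower and Hmgcs1, which encodes the early enzyme HMG-CoA synthase, 3.02-fold lower (1108 and 367). Oxidative phosphorylation genes had a smaller difference in the same direction, with 29 of 32 ratios under 0, 2 genes at least 2-fold lower and a median of -0.38 (random range -0.17 to 0.26). Cycs, which encodes cytochrome c, was 2.64-fold lower (2223 and 841) and Ndufa5 2.26-fold lower. For glycolysis the median was -0.39 (random range -0.30 to 0.38), with 3 of 18 genes at least 2-fold lower, among them the lactate dehydrogenase gene Ldha (3133 and 1401), and 1 at least 2-fold higher, the pyruvate dehydrogenase kinase gene Pdk1 (39.5 and 98.1). The glycolysis median changed sign, to 0.087, without probe sets that can read several transcripts.

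Eicosanoid metabolism genes had 7 of 17 members at least 2-fold higher and 2 at least 2-fold lower, with a median of 0.74 (random range -0.33 to 0.42). Pla2g4a, the cytosolic phospholipase A2 that releases arachidonic acid, was 2.52-fold higher (1676 and 4231), the prostaglandin dehydrogenase gene Hpgd 2.47-fold and the prostaglandin receptor genes Ptger2 and Ptger3 2.23-fold and 2.24-fold higher, while Pla2g7 was 5.77-fold lower and Alox5ap 2.85-fold lower (529 and 186). Among the 22 apoptosis regulators, 3 were at least 2-fold higher, Casp4 (24.6 and 124), Bbc3 (15.2 and 38.1) and Cflar (111 and 248), 0 were at least 2-fold lower, and the median was 0.55 (random range -0.31 to 0.34). Of 7 Hedgehog signalling genes, Gas1 was 2.38-fold higher (263 and 625) and the receptor gene Ptch1 had signals of 199.7 and 368, with a list median of 0.53 (random range -0.46 to 0.48). Under at least 1 alternative setting each of these 3 medians fell inside its random range, the eicosanoid one at 0.12 with members of other lists left out.

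Other genes among the 15 largest increases had various functions. Cmbl, which encodes a carboxymethylenebutenolidase-like hydrolase, was 28.8-fold higher (23.2 and 669.9), Stc1, which encodes the secreted glycoprotein stanniocalcin 1, 10.6-fold (48.8 and 519), Osbpl6 10.6-fold, the glutathione transferase gene Gsta2 9.49-fold (33.8 and 321), the semaphorin gene Sema3e 7.58-fold (55.4 and 419.6), Gldc, a glycine cleavage gene, 7.03-fold (74.4 and 523), Gask1b 6.63-fold and the alcohol dehydrogenase gene Adh1 6.63-fold higher. Ppp1r14c, Nsg2 and Tmem47 were under the floor in the control and at least 6.87-fold, 5.01-fold and 4.83-fold higher.

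Markers of other cell types were compared with the floor. The floor is set by the signals themselves, and 8304 of 12393 genes were over it on at least 1 array. A signal over the floor is therefore not by itself a detection of a cell type. Of 24 uterine stroma markers on the array, 20 were over the floor on at least 1 array, with a median log2 ratio of 0.26 (random range -0.33 to 0.43). The stromal matrix genes Dcn and Col3a1 had signals of 1235 and 1753, and of 570.0 and 721, and Fbln1 was 4.91-fold lower (219 and 44.5). The 6 measured smooth muscle markers had a median of -0.22 and the 5 lymphocyte and NK cell markers one of 0.04, both inside their random ranges. The 7 endothelial markers had a median of -0.05, which became 0.02 when each array was centred on its median. All 14 neutrophil and eosinophil markers and all 5 red blood cell markers on the array were under the floor on both arrays. Gland markers had a median of -0.18 and luminal epithelium markers one of -0.12, inside their random ranges. Of 11 measured gland markers, 1 was at least 2-fold higher, Spink1 as given above, and 4 at least 2-fold lower, among them Sprr2f, also given above, and Sox9 (at least 6.76-fold). Of 10 measured luminal epithelium markers, 0 were at least 2-fold higher and 4 at least 2-fold lower, Muc4 by at least 6.42-fold.

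**Figure D3:**
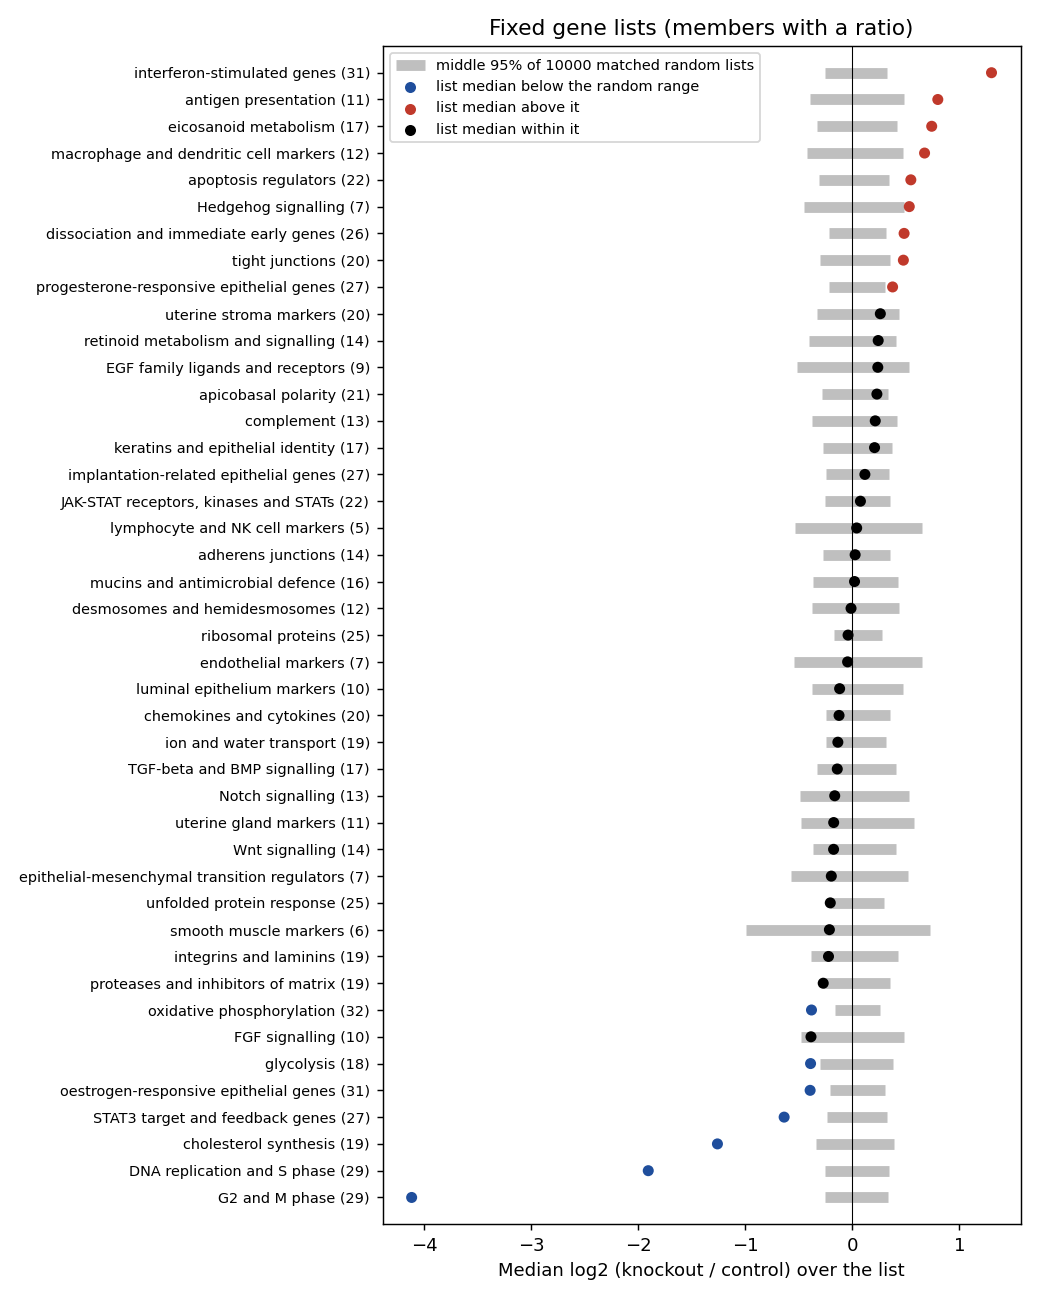
Median log2 ratio of knockout over control (horizontal) for the 43 gene lists with at least 5 measured members, with the number of members in brackets. Grey bars span the medians of 10000 random lists matched on mean signal, without 2.5% of them at each end. Below their bar lie 7 medians and above it 9, where 2.15 of 43 would lie outside if each list were a random draw of genes. The lists share members, and genes of 1 list can vary together, so this comparison is not a test of the groups.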

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

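The probe sets that the platform annotation pairs with no gene or with several genes entered no comparison of the report. Of these, 1095 were over the floor on at least 1 array, and 82 were at least 2-fold higher in the knockout than in the control array, a signal outside the main measurement; 96 were at least 2-fold lower. The probe set 1449009_at had signals of 99.5 in the control and 1799.9 in the knockout, a log2 ratio of 4.18. The probe set 1418536_at had signals of 39.8 and 770.2, a log2 ratio of 4.27. In the other direction, 1449254_at had signals of 789.6 and 24.4 (log2 ratio -5.02) and 1448205_at signals of 549.9 and 24.6 (log2 ratio -4.48). Their genes are not named here, and no explanation was tested.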

How the results depend on the processing

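The floor at a signal of 100 was chosen after seeing the data; the other settings were chosen before. The counts of genes past the limit, 612 higher and 824 lower, moved by over 1.5 times only with the floor or the fold limit, and not with any of the 3 other scalings: to 1094 higher with a floor at the 20th percentile, 346 higher and 449 lower at the 60th, 1927 and 1774 with no floor, 287 and 335 with a floor at a signal of 100, 1607 and 1541 at 1.5-fold, and 143 and 401 at 3-fold. Higher genes made up 42.6% of those past the limit in the main setting, 47.9% after median centring, 43.6% after quantile normalization and 36.7% after loess. Both measured Stat3 probe sets kept direction and limit in each of 8 settings. Of the 16 gene lists outside the random range, 10 stayed outside, on the same side, in every setting tried: G2 and M phase (medians of -4.17 to -1.94), S phase (-1.98 to -1.43), cholesterol synthesis (-1.35 to -0.86), STAT3 targets (-0.72 to -0.27), oestrogen-responsive genes (-0.69 to -0.34), oxidative phosphorylation (-0.41 to -0.32), interferon-stimulated genes (1.08 to 1.67), antigen presentation (0.60 to 0.93), tight junctions (0.44 to 0.63) and immediate early genes (0.45 to 0.55). The others lost that place in some settings. Hedgehog signalling had 0.46 with no floor, 0.16 with a pseudocount, 0.38 with the mean of all probe sets, and 0.53 both against unmatched random lists (percentile 95.8) and without members of other lists (percentile 97.3). Apoptosis regulators had 0.33 with the mean of all probe sets. Eicosanoid metabolism had 0.20 with the 60th percentile floor, 0.076 with the floor at 100, and 0.12 both without shared probe sets and without members of other lists. Glycolysis turned to 0.087 without shared probe sets. Macrophage markers had 0.063 with the 60th percentile floor and 0.47 without members of other lists. Progesterone-responsive genes had 0.28 with the 20th percentile floor and with none, 0.20 with a pseudocount, 0.33 without shared probe sets and 0.21 without members of other lists. The cause was not tested. Lists inside the random range came out of it in 18 cases and stayed in it in 289, FGF signalling and ion transport most often, below the range with lower floors or a pseudocount. Lists left with fewer than 5 measured members in a setting have no value there. No named gene past the 2-fold limit changed direction. The ratio of a named gene moved by over 1.5 times in 220 cases and stayed closer in 2459. Some named genes past the limit came inside it in a setting, among them Spink1 (log2 ratio 0.63), Aqp5 (-0.25), Timp1 (-0.13), Cd274 (0.24) and C1qa (0.07). Others stayed far past it, such as Lcn2 (-4.83 to -4.64) and Mki67 (-5.34 to -2.89). Signals near the floor of 14.0 limit all ratios of dim genes. No paired analysis was possible because each group had 1 array.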

Other observations

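Several further gene groups held members with large differences while their median lay inside the random range. Of 19 ion and water transport genes, 5 were at least 2-fold lower and 3 higher in the knockout. The potassium channel gene Kcnn4 was at least 21.3-fold lower from a control signal of 299, the chloride channel gene Cftr 6.34-fold lower (233 and 36.8) and the carbonic anhydrase gene Car12 4.86-fold lower (317 and 65.1), while Fxyd4, a regulator of the sodium pump, had signals of 5447 and 7472. Among 16 mucins and antimicrobial genes, 5 were at least 2-fold lower and 0 higher: besides Lcn2, Muc1 and Muc4, Muc20 was 7.56-fold lower and Pglyrp1 at least 2.31-fold lower, and the bright gene Wfdc2 had signals of 4807 and 4878. Of 14 retinoid genes, Crabp2, which encodes a retinoic acid binding protein, was at least 12.5-fold lower and Rdh11 3.93-fold lower, and Adh1 and Dhrs3 were 6.63-fold and 2.10-fold higher. Of 13 complement genes, Cfi was 10.6-fold lower (360.2 and 33.9) and Clu 3.40-fold lower, and C1ra, C1s1 and C1qa were 2.46-fold, 2.26-fold and 2.03-fold higher. Of 20 chemokines and cytokines, Csf3 was 3.18-fold higher (69.3 and 220.2) and Csf1 2.94-fold higher, and Cxcl14 was at least 2.99-fold lower.

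In the signalling lists, 4 of 17 TGF-beta and BMP genes passed the limit: Id1, an inhibitor of basic helix-loop-helix factors, was 6.13-fold lower (744 and 121) and its relative Id2 2.09-fold higher (752 and 1571), with a log2 ratio of -1.32 for the receptor gene Acvr1 and Bmp4 at least 2.20-fold higher. Of 10 FGF genes, the ligand gene Fgf1 was 5.51-fold higher (211 and 1166) and the receptor gene Fgfr2 2.26-fold higher (506 and 1144), while Etv5 and Spry1, which respond to FGF signals, were 2.55-fold and 2.32-fold lower. Of 13 Notch genes 4 were at least 2-fold lower, among them Notch3 (48.4 and 17.4), and of 14 Wnt genes 2, Lgr5 (48.2 and 17.8) and Wnt7b (38.9 and 17.9). Matrix proteases and their inhibitors had a median of -0.27, just inside the random range, with Plaur 2.63-fold and Plat 2.08-fold lower and Timp3 3.17-fold higher. Of 19 integrins and laminins, Lamb1 was 3.05-fold lower and Itgb5 2.58-fold higher. The median of the unfolded protein response list, -0.21, also lay just inside, with the chaperone gene Hspa5 2.12-fold lower (3219 and 1521). Of 7 genes of epithelial-mesenchymal transition, Fn1 was 2.11-fold lower. All 25 ribosomal protein genes lay within 2-fold, with a median of -0.04, which became 0.02 under median centring.

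All tests in this and the following 2 paragraphs were chosen after the results were seen. The cell cycle genes together had a median log2 ratio of -3.24 (58 genes of both lists). A scaling or brightness bias between the arrays was argued against, as the median stayed at -3.17 or lower under each of 3 other scalings. More cells of other types, with dividing ones among them, in the control pool would lower the markers of those cells in the knockout alike. Against this, 50 markers of stroma, muscle, vessels, macrophages and lymphocytes had a median of 0.22 (robust SD 0.62). The medians were 0.26 for 20 stroma markers and 0.67 for 12 of macrophages and dendritic cells. They were -0.22 for 6 muscle markers, -0.05 for 7 of vessels and 0.04 for 5 of lymphocytes and NK cells. These few markers do not decide about muscle, vessels or lymphocytes. A different rate of division in an equal number of cells of other types stays open. Pools of different hormonal stage, apart from genotype, cannot be told apart from the deletion with 1 pool per genotype: oestrogen-responsive genes outside the cell cycle and progesterone lists had a median of -0.40 (29 genes) and progesterone-responsive genes one of 0.45 (26 genes), a difference of -0.84, so that the lower cell cycle genes may belong to such a shift or to the loss of Stat3.

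The interferon-stimulated genes had a median log2 ratio of 1.30 in the knockout. More macrophages or dendritic cells in the knockout pool are argued against as the whole cause. Of the 17 measured leukocyte markers, 12 of them markers of these cells, 0 were at or above the median of the interferon-stimulated genes. The median of the 17 was 0.46 and the highest, C1qa, had 1.02. Cd14 and Lyz2, the brightest markers that were higher, had 0.74 and 0.95. Of the 12 macrophage and dendritic cell markers, 10 had a ratio over 0 and 2 under it, Laptm5 among these (227 and 118, log2 ratio -0.95). Only 5 lymphocyte and NK cell markers were measured, 3 with a ratio over 0 and 2 under it. Klrd1 (16.7 and 21.5) and Ighm (16.3 and 16.8) were near the floor. Cd79b was at least 3.17-fold lower (44.5 and 7.79), and Jchain had signals of 25.7 and 10.8. The other 12 on the array and all 14 neutrophil and eosinophil markers were under it on both arrays, so the values cannot decide about those cells. The same number of leukocytes in a more active state was not tested. Another MHC haplotype read by the probe sets is argued against as the whole cause. The 27 interferon-stimulated genes outside the MHC had a median of 1.18. That median leaves out Tap1, Tap2, Psmb8 and Psmb9, so the haplotype stays open for these and for other MHC genes such as H2-K1 and H2-D1. An infection or another immune stimulus in the knockout pool, apart from genotype, cannot be told apart from an effect of the deletion: 0 of 14 neutrophil and eosinophil markers were over the floor in the knockout, which does not exclude a stimulus without granulocytes, and there was 1 pool per genotype. An effect of the deletion itself was not tested apart from these.

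The Stat3 signal that remained in the knockout was 186 and 160.0 on its measured probe sets. Cells that kept the gene could contribute, stroma among them if the deletion spared it, which was not determined here. In the knockout, 19 of 24 stroma markers (79.2%) were over the floor, with Dcn at 1753. Of all probe sets that are not controls, 60.2% were over it on that array. The share of stroma in the RNA is unknown. Such cells cannot be told apart from incomplete deletion in the epithelium or from transcripts that still carry the probed part. These last 2, and background specific to each probe set, were not tested.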
